A study of Macaca radiata with 4 samples.

How the data were processed

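RNA from corpora lutea of female bonnet monkeys (Macaca radiata) was measured on 4 Affymetrix rhesus macaque arrays, 2 from animals given CET and then PBS and 2 from animals given CET and then rhLH. Total RNA was extracted with Trizol, cleaned on columns and labelled with biotin, per the labels' protocols. The deposited values are probe set intensities, which are MAS5 signals on a linear scale per the submitters' processing notes. The 2% trimmed mean of the deposited signals was the same on all 4 arrays to within rounding (500.0), so the arrays were matched in this measure. Their distributions still differed: the 99th percentile of signals was 8886 on PBS replicate 1 and 12091 to 12459 on the others. The scaling target, detection calls and any filter are not given in the sources used here.

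Signals entered the tests as log2(signal + 16) with no further normalization, because the 4 trimmed means lay within 10% of each other. Of 52865 probe sets, 99 control probe sets were set aside for quality checks. Probe sets were kept when their mean log2 over the 4 arrays lay above the 40th percentile, equal to a signal of 90.7, which left 31659. Gene symbols came from a platform annotation provided for the array: of 52766 probe sets considered, 24956 had 1 symbol, 361 had several and 27449 had none. Those kept with 1 symbol covered 10998 genes, and a gene was represented by its brightest kept probe set. No genome was used, so no coordinates are given. Probes were designed for the rhesus macaque, and mismatches to the bonnet monkey sequence were not examined here.

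Groups were taken from the sample titles, and the comparison was rhLH against PBS. Probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold adjusted p of 0.05). A 2-fold rule counted probe sets for which every rhLH array differed at least 2-fold, in one direction, from every PBS array. Of 32 gene lists (20 pathways and 12 sets of cell type markers, 743 genes, 467 of them kept), the 30 with at least 5 kept genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Each list's median was also placed among 10000 random lists of the same size matched on mean expression in 20 bins. Fold differences are differences of mean log2 values put back on the linear scale, and SDs are over the 2 arrays of a group.

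The test, the filter, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the text names the 10 genes per direction with the largest difference among those past the adjusted threshold, filled where too few pass by ascending p from genes with unadjusted p under 0.01 whose groups do not overlap. It also names up to 4 members per list that passed the test, or where none passed the 2 with the smallest p, and a panel of 12 genes where measured. All other genes named were chosen after their values were seen and are marked so. The labels describe 2 animals per group but do not tie each array to an animal. The limma p-values of single probe sets therefore measure the spread between these arrays, part of which can be technical. Camera at the preset correlation sets the genes of a list against all other kept genes. Its p-values therefore rest on the spread over genes and do not measure the spread between animals. With 2 arrays per group, their number limits the precision of every value.

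The pipeline was tested on simulated data with 67 probe sets changed 2-fold, 67 changed 4-fold and 66 changed 8-fold among the 31659. With 4 arrays alike in noise, limma recovered 8.96%, 71.6% and 86.4% of them, with 6 false calls. Without PBS replicate 1 and with the other 3 alike, it recovered 5.97%, 59.7% and 77.3%, with 14 false calls. With the noise of PBS replicate 1 set to that measured (SD 1.11 on the log2 scale, against 0.36 for the other 3 arrays), it recovered 0 at each size, with 0 false calls. For lists of 20 genes shifted by 1 on the log2 scale, camera recovered 10 of 10 with the preset correlation and 0 of 10 with an estimated correlation. Among 20 unshifted lists there were 0 false calls in either case. The loss of a call with an estimated correlation therefore does not weigh against that call. Simulated probe sets of similar level shared 1 SD, whereas in the data the SDs of such probe sets differed (3.87 prior degrees of freedom in limma). The recovery with arrays alike in noise can therefore be too high for these data. Noise was drawn for each gene on its own, so the 0 false calls do not cover lists whose members vary together. The shift of 1 also exceeds the medians of the lists called below. Alternatives covered quantile normalization, arrays centred on their medians, pseudocounts of 1 and 64, no filter and a filter at the 70th percentile, other variance priors, array weights, other thresholds, another choice of probe set per gene, and leaving out each array in turn. With 1 array left in a group, that array was assumed to vary like the pair in the other group. The rule that read the bright gene explanation of the list differences was revised after a first run: the 2 lists it had joined were split, and a cut-off on the share of the median left by quantile normalization, chosen with those values in view, was added to the percentile among matched random lists. The test of the poly-A controls was likewise widened from 3 probe sets to all of them after its first value was seen, and the explanation by another tissue was narrowed to tissue that makes no steroids.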

Results

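All animals received CET, which per the labels blocks the animal's own LH secretion, at 150 µg/kg on day 7 of the luteal phase. At 24 h they were injected with 20 IU/kg of rhLH, a recombinant LH, or with PBS as the vehicle, and the corpus luteum was collected 8 h later. Replicates 1 and 2 form the PBS group and replicates 3 and 4 the rhLH group. Each array gave a signal for 52865 probe sets, with median signals of 186 and 139.5 on the PBS arrays and 136 on both rhLH arrays. PBS replicate 1 correlated less with the other 3 arrays (Pearson r across kept probe sets 0.752, 0.756 and 0.780) than these did with each other (0.940, 0.947 and 0.947). Therefore medians of called lists are also given against each PBS array, as are those of all tested lists in the figure. For a gene named from a list, 2 values in brackets are its log2 differences against PBS replicate 1 and against PBS replicate 2.

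The comparison asked which luteal transcripts differ when LH is given back after its withdrawal. FST, which encodes the activin-binding protein follistatin, had a mean signal of 3780.2 ± 196 (SD, n = 2) with rhLH and 1064 ± 237 (SD, n = 2) with PBS, a 3.56-fold difference (log2 1.83, SE 0.33). WNT5A, a secreted Wnt ligand, was 4.24-fold higher on the rhLH arrays (5075 ± 1689 against 1173 ± 328), and ALAS1, the first enzyme of heme synthesis, was 3.36-fold higher (5214 ± 737 against 1577 ± 541). BCL10, an adaptor protein of NF-kB signalling, was 3.00-fold lower with rhLH (739.5 ± 8.73 against 2283 ± 563), and HTR2B, a serotonin receptor, had signals of 77.5 and 123 with rhLH against 1088 and 541 (log2 −2.78), the first below the filter level of 90.7. The arrays of the groups did not overlap for these 5 genes, which the naming rule required and which is therefore no support. No probe set passed the limma test, whose smallest adjusted p was 0.919.

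Of the other genes the naming rule gave on the higher side, ADA, which deaminates adenosine, was 5.20-fold higher with rhLH (log2 2.38, SE 0.44) and AMDHD1, an enzyme of histidine breakdown, had a log2 difference of 3.26 (SE 0.65), which was 2.52 without PBS replicate 2 and 3.999 without PBS replicate 1. Its signal on PBS replicate 2 (78.9) and that of RAPGEF4 on rhLH replicate 4 (89.4) lay below 90.7. MYOM1, a muscle M-band protein, had a log2 difference of 2.10, the chloride channel protein CLIC5 1.72, the lipase ABHD6 1.49, the mRNA-binding protein CPEB4 1.36 and the smooth muscle protein TAGLN 1.27. On the lower side, PYROXD1, an oxidoreductase, differed by −2.38, AFF2 by −2.17, RAPGEF4, an exchange factor activated by cAMP, by −2.01, POLR3B, a subunit of RNA polymerase III, by −2.01, LOC714817 by −1.90, ATN1 by −1.87, the kinase STK17B by −1.72 and NR1D1, a repressor of the circadian clock, by −1.46. Of 21 further probe sets of these 20 genes, 4 lay on the opposite side, at 1.10 for ATN1, 0.59 for RAPGEF4, 0.31 for AFF2 and −0.07 for ADA. That of PYROXD1 stood at −0.25, and 2 of the 4 of CLIC5 at 0.08 and 0.21. Both further probe sets of FST (2.26 and 1.24) and of WNT5A (1.75 and 1.45) lay on the same side, as did the further probe set of BCL10 (−1.94). The rule also gave 8 probe sets with no gene symbol. On the lower side these were MmugDNA.24664.1.S1_at, with signals of 15907 and 15234 on the PBS arrays and 4476 and 4002 on the rhLH arrays, MmugDNA.5294.1.S1_at (log2 −2.17) and MmugDNA.30388.1.S1_at (log2 −3.31, both rhLH signals below 90.7). On the higher side they were MmugDNA.25667.1.S1_at (log2 2.75), MmugDNA.17404.1.S1_s_at (1.96), MmugDNA.19588.1.S1_at (1.87) and 2 more, at 2.36 and at 3.32, the latter ranked first of all probe sets in the limma test (adjusted p = 0.919).

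**Figure D1:**
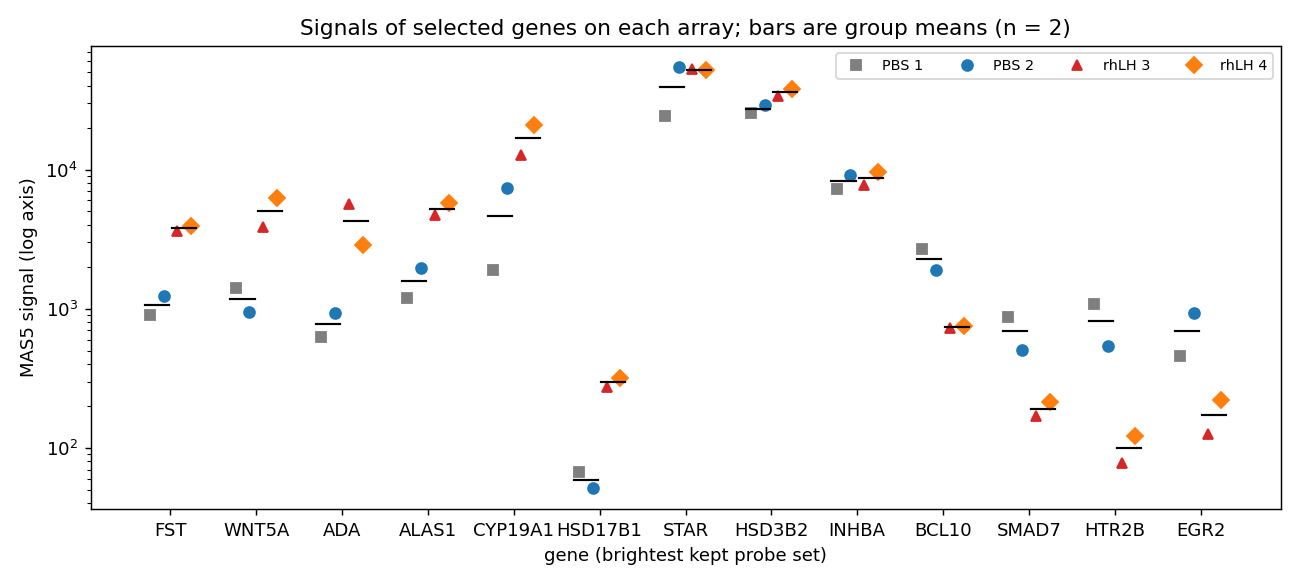
MAS5 signals (log axis) of 13 genes on each of the 4 arrays, with a bar at each group mean (n = 2). FST lies at 3642 and 3919 on the rhLH arrays against 896 and 1231 on the PBS arrays, whereas the STAR signal of PBS replicate 2 (54566) lies above those of both rhLH arrays (52570.3 and 51660).

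Across the 31659 kept probe sets, limma made 0 calls at an adjusted p of 0.05. With the noise of PBS replicate 1 it also recovered 0 of the simulated changes, so these 0 calls do not show that no transcript differed. An unadjusted p under 0.05 was found for 641 probe sets (278 higher and 363 lower with rhLH), where chance alone gives 1583. This count rests on all 4 arrays, the noisy PBS replicate 1 among them, so the shortfall does not show that few transcripts differed. By the 2-fold rule, 109 probe sets were higher and 155 lower on both rhLH arrays. Counted by the brightest kept probe set of each gene, 35 genes were higher and 37 lower. The other 2 ways of splitting the 4 arrays in pairs gave totals of 216 and 287, against 264 for the real groups, and the groups did not overlap for 32.2% of probe sets, where chance gives 33.3%. Taking PBS replicate 2 as the sole control left 0 adjusted calls, and taking PBS replicate 1 as the sole control gave 8169.

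Of the fixed panel of luteal genes, 4 were measured. CYP19A1, the aromatase that makes estrogens, was 4.32-fold higher with rhLH (16759 ± 5782 against 4658 ± 3922, n = 2 each; log2 2.11, SE 0.69), by 3.10 on the log2 scale over PBS replicate 1 and by 1.13 over PBS replicate 2. STAR, which carries cholesterol into the mitochondrion, had a log2 difference of 0.52 (SE 0.53), made up of 1.10 against PBS replicate 1 and −0.07 against PBS replicate 2. HSD3B2, which makes progesterone, differed by 0.40 (SE 0.39; 0.50 and 0.30 against the 2 PBS arrays) and INHBA, the inhibin and activin βA subunit, by 0.07 (SE 0.34) on its brightest probe set and by 1.10 on the other. On the latter the difference was 2.65 against PBS replicate 1 and −0.44 against PBS replicate 2. HSD3B2 moved to −0.01 under quantile normalization and the brightest INHBA probe set to −0.09, and the limma adjusted p was 0.972 for that probe set and 0.919 for the other one and the other 3 genes. The other 8 panel genes, the LH receptor gene LHCGR among them, were not matched to a kept probe set with the annotation used here and were not analysed.

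Genes of granulosa-lutein cells and of steroidogenesis had median log2 differences of 0.79 over 8 genes (adjusted p = 0.0163, limma camera at the preset correlation) and 0.41 over 18 genes (adjusted p = 0.0305). Neither call held with an estimated correlation (adjusted p = 0.799 for both, the upper end of ranges from 0.00493 and 0.00553 over all alternatives) or by fry (0.779). In the simulated data an estimated correlation recovered 0 of 10 shifted lists, so its loss weighs against neither these calls nor those below. Against PBS replicate 1 alone the medians were 1.40 and 1.03, and against PBS replicate 2 alone they were 0.23 and 0.02. Of the granulosa-lutein markers 4, CYP19A1, HSD17B1, AMHR2 and NR5A2, were higher on both rhLH arrays than on both PBS arrays, the last 2 named here after their values were seen. All of these but AMHR2 are also in the steroidogenesis list, so the 2 calls are not separate results. Of the steroidogenesis genes 7 lay above and 3 below both PBS arrays. HSD17B1, which converts estrone to estradiol, had signals of 273 and 319 with rhLH and of 67.1 and 51.4 with PBS. Both of the latter lay below 90.7, and its log2 difference ran from 1.55 to 2.31 with the pseudocount. In either list 0 single members passed, over all probe sets or adjusted over the list alone. Of the 5 list calls made with the preset correlation, 0 were kept under quantile normalization and 0 without PBS replicate 1. The steroidogenesis call was also lost without rhLH replicate 4 (adjusted p = 0.0814).

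Respiratory chain and ribosomal protein genes had medians of 0.34 over 29 genes (adjusted p = 0.0364, camera) and 0.35 over 30 genes (adjusted p = 0.0367). Neither call held with an estimated correlation (adjusted p = 0.799 and 0.829, within ranges of 0.00593 to 0.990 and 0.00179 to 0.829 over all alternatives). Leaving out rhLH replicate 4 also ended both (0.185 and 0.0961), and leaving out rhLH replicate 3 the ribosomal call (0.0556). The medians were 0.70 and 0.84 against PBS replicate 1 and 0.00 and −0.12 against PBS replicate 2. Few members separated the groups: 4 respiratory chain genes lay above both PBS arrays and 1 below, as against 3 and 1 of the ribosomal genes. The genes named by the rule were NDUFB6 of complex I (1.69 and 0.17), UQCRB of complex III (0.53 and 0.47), RPL8 (2.09 and 0.03) and RPS16 (−0.95 and −0.66), whose pooled −0.80 became −0.22 without rhLH replicate 3. The 2 further probe sets of UQCRB had pooled differences of −0.77 and −0.10, opposite to the first.

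Cytokine and chemokine genes formed the only tested list called lower (median −0.35 over 23 genes, adjusted p = 0.0326, camera). The call did not hold with an estimated correlation (adjusted p = 0.799) or by fry (0.779), within a range of 0.0248 to 0.799 over all alternatives. Leaving out PBS replicate 1 gave 0.206, PBS replicate 2 0.0951 and rhLH replicate 4 0.0961. IL18 had a log2 difference of −1.32 (158 ± 9.76 against 423 ± 93.1, n = 2 each), made up of −1.54 and −1.10 against the PBS arrays. IL6 (−3.06 and −1.08) had signals of 26.1 and 84.0 with rhLH, both below 90.7. Its pooled difference of −2.07 became −1.45 without rhLH replicate 3 and −2.69 without rhLH replicate 4. In all, 9 members lay below both PBS arrays while 0 lay above. The median was −0.40 against PBS replicate 1 and −0.36 against PBS replicate 2. Among random lists matched on expression these stood at percentiles 16.8 and 0.08, so the first did not stand out for genes of that level. Quantile normalization moved the median to −0.12 and ended the call.

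The median of immediate response genes of cAMP signalling took opposite signs against the 2 PBS arrays. EGR2, a zinc finger transcription factor (−1.36 and −2.37), and MYC (−0.57 and −1.39) were lower against both, and the median over 26 genes was −0.27 (adjusted p = 0.265, camera). The list median was 0.21 against PBS replicate 1 and −0.62 against PBS replicate 2. Without PBS replicate 1 it was the single list called (adjusted p = 3.67e-06, within a range up to 0.840 over all alternatives), and 0 lists were called there with an estimated correlation. Genes of LH receptor and cAMP signalling showed no common direction, with a median of −0.09 and a mean of 0.03 (adjusted p = 0.988). RGS2, which dampens G protein signals, was 2.52-fold higher (log2 1.34, SE 0.57), by 2.12 over PBS replicate 1 and 0.55 over PBS replicate 2, and its further probe set stood at 0.35.

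Ovulatory LH targets, genes known from the response of follicles to the LH surge, had a median of −0.33 over 18 genes (adjusted p = 0.100, camera), with 8 members below both PBS arrays and 3 above. AREG, an epidermal growth factor family ligand, was 2.41-fold lower with rhLH (9954 ± 4442 against 23375 ± 7618, n = 2 each; log2 −1.27, SE 0.48, made up of −0.93 and −1.60), and the protease ADAMTS1 was 1.83-fold lower (log2 −0.87, SE 0.32, made up of −0.95 and −0.79). The AREG difference became −0.80 without rhLH replicate 3. Of the cholesterol synthesis genes, the rule named HSD17B7 (1.22 and 0.96) and MVD (0.94 and 0.64). The further probe sets of HSD17B7 had pooled differences of 0.20 and 1.74. Cholesterol synthesis genes had a median of 0.38 over 17 genes (adjusted p = 0.0718, camera), 15 of them with a positive difference. That median was 0.58 without rhLH replicate 3, where the list was called (adjusted p = 0.00553, within a range up to 0.799 over all alternatives), 0.09 without rhLH replicate 4 and 0.08 without PBS replicate 1. Genes of cholesterol uptake and transport had a median of −0.19 (adjusted p = 0.270), with VLDLR, a lipoprotein receptor (−1.49 and −0.67), and MYLIP, a ubiquitin ligase (−2.23 and −0.59), whose further probe sets had pooled differences of −0.14 and −0.12.

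In the activin, inhibin and BMP list, FST was higher and SMAD7, which inhibits TGF-beta signalling, was 3.30-fold lower with rhLH (log2 −1.72, SE 0.47, made up of −2.11 and −1.33), and the median over 30 genes was 0.06 (adjusted p = 0.749). FST was the only member of that list to pass when limma p-values were adjusted over the list alone, and TAGLN the only one among the pericyte and smooth muscle markers. Over all lists these were 2 of 467 genes, and over all probe sets 0 passed. The further probe set of TAGLN stood at 2.33 against PBS replicate 1 and at −0.14 against PBS replicate 2. Genes of oxidative stress defence had a median of 0.38 (adjusted p = 0.0718), 0.86 against PBS replicate 1 and −0.14 against PBS replicate 2, with the metallothionein MT2A (3.10 and 0.78) and the glutathione synthesis gene GCLM (0.60 and 0.49; pooled 0.34 without rhLH replicate 3). Without PBS replicate 2 that list was called (adjusted p = 0.00593, within a range up to 0.829). Cell cycle genes had a median of −0.33 (adjusted p = 0.100), with AURKB (−1.80 and −0.39) and TOP2A (−1.02 and −0.52), whose further probe set had a pooled difference of 0.33. TOP2A moved to −0.23 without rhLH replicate 3, and the list was called without rhLH replicate 4 (adjusted p = 0.0469, within a range up to 0.799).

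The remaining pathway lists did not pass the camera test. The median was 0.43 for luteal hormones and receptors (adjusted p = 0.206), with IGFBP4 (1.57 and 0.31) and ESR2 (1.45 and 0.64). It was 0.34 for glycolysis (adjusted p = 0.144), with TPI1 (2.04 and −0.04) and PDK1 (−1.15 and −1.05), whose pooled −1.10 became −0.38 without rhLH replicate 3. It was 0.28 for heat shock genes (adjusted p = 0.206), with STIP1 (0.83 and 0.45) and DNAJA1 (0.53 and 0.65). It was 0.26 for the unfolded protein response (adjusted p = 0.270), with SDF2L1 (2.15 and 0.42) and HERPUD1 (−0.41 and −0.88). It was 0.16 for apoptosis (adjusted p = 0.749), with TNFRSF10A (1.26 and 0.73) and PMAIP1 (−1.004 and −0.71). It was 0.13 for matrix remodelling (adjusted p = 0.749), with ADAMTS5 (−0.72 and −0.93), and its median was 0.29 against PBS replicate 1 and −0.24 against PBS replicate 2. It was −0.42 for the prostaglandin pathway (adjusted p = 0.346), with PLA2G2A (1.45 and 0.29) and PTGFRN (−0.65 and −0.43), whose further probe set had a pooled difference of 0.22. Angiogenic and vasoactive genes had a median of −0.04 and a mean of 0.08 (adjusted p = 0.963), with ANGPTL4 (1.85 and 0.75) and the angiotensin receptor gene AGTR1 (−0.83 and −0.62). The further probe set of ANGPTL4 stood at 3.88 against PBS replicate 1 and at 0.09 against PBS replicate 2. Without rhLH replicate 3, PTGFRN moved to −0.04, AGTR1 to −0.33 and DNAJA1 to 0.29, and the lists of luteal hormones and of glycolysis were called (adjusted p = 0.0405 and 0.0490, within ranges up to 0.949 and 0.990). Without PBS replicate 1, 12 of the 30 list medians changed sign, among them those of matrix remodelling, luteal hormones, apoptosis, oxidative stress defence and activin signalling.

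Markers of other cell types did not pass either. Median log2 differences were 0.12 for theca-lutein cells (adjusted p = 0.749), 0.26 for endothelial cells (0.265), 0.22 for pericytes and smooth muscle (0.540), −0.15 for fibroblasts (0.358), 0.19 for macrophages (0.494), 0.07 for T and NK cells (0.749), 0.07 for neutrophils and mast cells (0.749), 0.19 for adipocytes (0.749) and 0.15 for epithelial cells (0.265). Macrophage markers stood at 1.11 against PBS replicate 1 and −0.25 against PBS replicate 2, and endothelial markers at 0.27 and −0.07. Named members were KDR (2.4996 and 0.20) and CLDN5 (1.27 and 0.12) of endothelium, CD68 (1.17 and 0.31) and CD14 (1.47 and 0.07) of macrophages, GZMB (1.82 and 0.55) and GZMA (−0.09 and −0.41) of T and NK cells, TCF21 (−2.31 and −1.35) and COL3A1 (−1.50 and −0.28) of fibroblasts, and the keratins KRT8 (2.87 and 0.63) and KRT18 (1.17 and 0.59). CNN1 (2.17 and −0.01), S100A9 (2.15 and −0.37), KCNK2 (−1.37 and 0.06) and ADIPOQ (−0.75 and 0.17) took opposite signs against the 2 PBS arrays, LPL (0.08 and 0.63) and GZMA changed sign without rhLH replicate 3, and S100A8 stood at −0.10 and −0.41. The further probe set of CD68 (pooled −0.99), all 3 of GZMA, all 3 of LPL and 1 of ADIPOQ lay on the side opposite to the pooled difference of the first. That of KRT18 had a pooled difference of 0.18, against 0.88 on the first. Both rhLH signals of TCF21 lay below 90.7. Without rhLH replicate 3, CD68 moved to 0.25 and CLDN5 to 0.43, and without PBS replicate 1 the medians of theca-lutein, endothelial, pericyte, macrophage and T and NK cell markers changed sign. Lists for B and plasma cells and for red cells had 4 and 3 kept genes and were not tested.

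**Figure D2:**
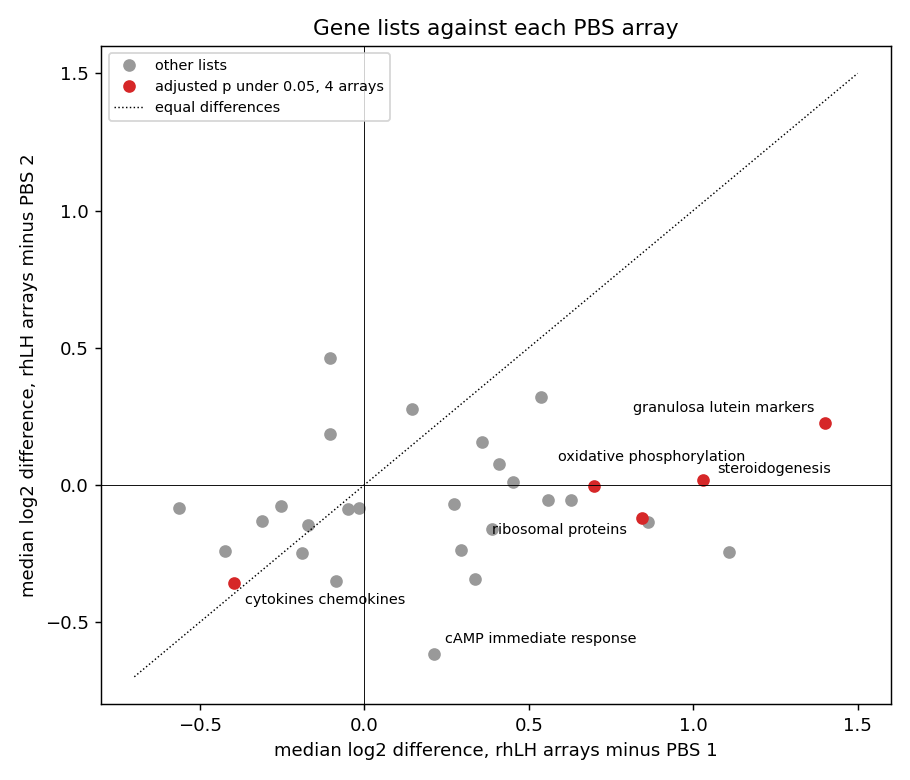
Median log2 difference of each of the 30 tested gene lists, rhLH arrays minus PBS replicate 1 on the horizontal axis and minus PBS replicate 2 on the vertical axis. The 4 lists called higher lie between 0.70 and 1.40 against PBS replicate 1 and between −0.12 and 0.23 against PBS replicate 2, and the cytokine list alone lies near the line of equal differences among the 5 called.

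PBS replicate 1 stood apart from the other 3 arrays. The first principal component, with 74.2% of the variance, separated it from the rest, and 34.4% to 37.9% of kept probe sets differed over 2-fold between it and each other array, against 8.28% to 9.67% in the other pairs. Probe sets are not independent replicates, so the correlations above carry no test. The 3′ over 5′ signal ratio of the ACTB control probe sets was 11.2 on that array and 1.49, 1.59 and 1.54 on the others, that of GAPDH was 3.23 against 1.88, 2.28 and 1.62, and that of EF1A was 1.06 against 0.949, 0.933 and 0.884. The poly-A control dap, spiked in before labelling, had a signal of 7.26 there and 963 to 1225 elsewhere, a rhesus version of its probe set 116 there and 1068 to 1529 elsewhere, and the rRNA probe set brightest elsewhere 42.3 there and 8960.4 to 11782 on the other arrays, whereas the hybridisation control cre had 17114 against 23380 to 27523.

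**Figure D3:**
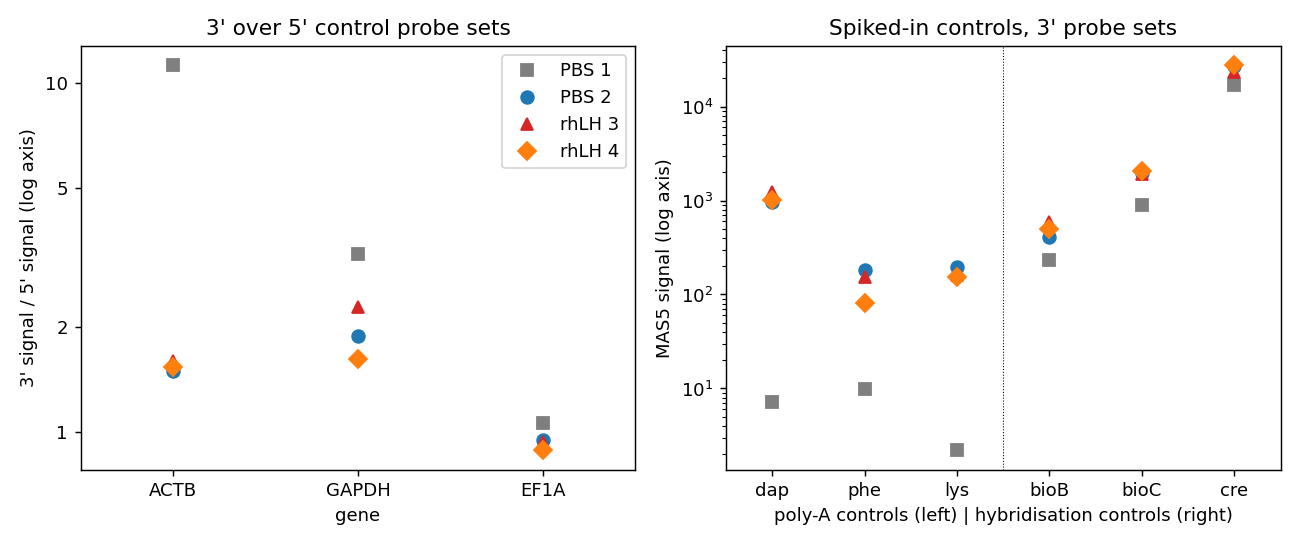
Left, the ratio of 3′ to 5′ signal (log axis) of the control probe sets of 3 genes on each array; right, MAS5 signals (log axis) of poly-A and hybridisation spike-in controls. PBS replicate 1 has the highest ratio for each gene (11.2 for ACTB) and the lowest signal for each spike-in shown (7.26 for dap).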

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

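The tests weighed in this part were chosen after the values were seen. Control probe sets outside the comparison had signals at least 2-fold higher on both rhLH arrays than on both PBS arrays in 4 cases. The lowest rhLH signal over the highest PBS signal was 5.86 for AFFX-Mmu-r2-Bs-lys-M_at (123 and 132 against 4.69 and 20.99) and 2.63 for AFFX-r2-Bs-lys-5_at (92.5 and 75.4 against 0.991 and 28.7). It was 2.84 for AFFX-r2-TagJ-3_at (68.8 and 60.2 against 17.5 and 21.2) and 2.32 for AFFX-TrpnX-3_at (31.7 and 9.68 against 1.63 and 4.17). All 8 of these PBS signals lie below 90.7, the level of the filter.

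PBS replicate 1 departed from the other 3 arrays. A sample of tissue that makes no steroids in its place is argued against by STAR, HSD3B2 and FDX1, the lowest of which stood at percentile 99.7 among genes on that array. Other steroid-making tissue is not excluded by them and stays open. CYP19A1 stood at percentile 79.2 there (95.3 to 98.97 elsewhere), and RLN2 had a signal of 19155 (18901 to 28681). CYP11B2 had 2552 (241 to 296) and was among the genes that lay farthest above the other arrays. The related CYP11B1 did not stand out there, with 600 and 312 on its probe sets against 722 and 254 on PBS replicate 2 and higher signals on both rhLH arrays. Breakdown of the RNA or labelling biased to the 3′ end may account for part of it, since 3 of 3 genes had a higher 3′ over 5′ ratio there than on every other array, although EF1A was only slightly higher (1.06 against 0.949, 0.933 and 0.884), and all 4 rRNA probe sets were lower there (42.3 against 8960.4 to 11782 for the one brightest elsewhere), which no test weighed. A labelling run without poly-A spike-in controls stays open: over all 36 poly-A probe sets the gap to the hybridisation controls was −1.59 on the log2 scale, while it was −3.44 for dap, −1.66 for phe, −0.77 for lys and −0.63 for thr (9 probe sets each) and −5.19 over 3 probe sets on which this was first read, before all were taken, and the brightest of dap (116) lay below the brightest Tag control (379.7) on that array. Apart from the kind of tissue, no biological explanation was tested, because the labels set this sample apart in no way.

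Steroidogenesis, granulosa-lutein, respiratory chain and ribosomal genes were called higher with rhLH as lists at the preset correlation, and all 4 calls were lost with an estimated correlation (adjusted p = 0.799 to 0.829, within 0.00179 to 0.990 over all alternatives) and by fry (0.779). The loss with an estimated correlation decides nothing, since that setting recovered 0 of 10 shifted lists in the simulated data. PBS replicate 1 alone may account for the 4 calls, although the lists were not alike without it. Against PBS replicate 2, the granulosa-lutein median stood at percentile 96.85 among random lists matched on expression. The medians of steroidogenesis, respiratory chain and ribosomal genes stood at 58.4, 35.4 and 2.14. The largest of the 4 medians against PBS replicate 2 was 0.23, while the smallest against PBS replicate 1 was 0.70. A loss of signal from bright genes on that array may explain the ribosomal and respiratory chain lists. Their medians stood no higher than percentile 94.6 among random lists matched on expression. Under quantile normalization they fell to 0.11 (SD over members 0.31, from 0.35 with SD 0.35) and 0.22 (0.40, from 0.34 with 0.39). Against PBS replicate 1 alone, however, the percentiles were 98.9 and 96.9, so for the ribosomal list the explanation stays open. For granulosa-lutein markers the percentile was 99.99, and the median was 0.68 (SD 0.93) after quantile normalization, from 0.79 (SD 0.90). The call ended there (adjusted p = 0.0605, camera), and the reason was not tested. These values cannot decide, since the list was picked for its high median. Members of random lists were also drawn independently, while members of a real list can vary together. Ovulatory LH targets and cAMP immediate response genes, not called on the 4 arrays, stood at percentiles 0.05 and 0.09. The bright gene explanation therefore stays open for granulosa-lutein markers. For steroidogenesis, percentile 97.9 and a quantile-normalized median of 0.26 (SD 0.76, from 0.41 with 0.73; adjusted p = 0.209, within 0.00553 to 0.799) point different ways and leave it open, and an effect of LH itself on these lists stays open as untested. The test of bright genes was changed once its first outcome was seen: it first read the percentile alone, with steroidogenesis and granulosa-lutein genes together, and argued against the explanation for both, and the share of the median left by quantile normalization (62.6% and 86.4%) was then added with its cut-off, which turned steroidogenesis to open.

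Probe sets at least 2-fold apart from both PBS arrays numbered 264, and 2 of the 3 ways of splitting the 4 arrays in pairs, the real one included, gave as many, the highest other count being 287. The 3 splits are too few for a share under 0.05. Of 41 further probe sets of 26 of the same genes, 33 had the same sign (80.5%, exact Clopper-Pearson 95% interval 65.1% to 91.2%), with 66.7% and 63.3% in the other splits. This share argues against noise of single probe sets as the whole explanation. The interval treats the probe sets of 1 gene as independent, which they are not, so it can be too narrow. Probe sets of 1 gene share their samples, so differences between animals unrelated to LH and an effect of LH replacement both stay open.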

How the results depend on the processing

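No alternative was chosen after the values were seen. Since limma recovered 0 simulated changes with the noise of PBS replicate 1, a count that stays at 0 does not show that no transcript differed. Array weights could not set that array apart, because both PBS arrays received the same weight (0.41). The count of limma calls at adjusted p 0.05 stayed at 0 in every alternative except leaving out PBS replicate 2 (8169; range over left-out arrays 0 to 8169), which makes PBS replicate 1 the sole control; unadjusted p under 0.01 with at least 2-fold gave 80 probe sets. Probe sets past the 2-fold rule, 109 higher and 155 lower, became 65 and 58 with a pseudocount of 64, 378 and 798 with no filter, 42 and 19 with the filter at the 70th percentile, and 407 and 693 at 1.5-fold (fewer or more probe sets qualify by construction). With each array left out, and so fewer ratios to meet, they ranged from 223 to 4140 and from 344 to 4391. The share on the higher side was 41.3% as deposited, 56.3% after quantile normalization, 32.1% with no filter, 68.9% with the filter at the 70th percentile, 68% without PBS replicate 1 (731 higher and 344 lower) and 23.7% without rhLH replicate 3 (223 and 717), so the balance of the 2 directions did not hold. The 5 list calls became 0 with quantile normalization, 0 with the filter at the 70th percentile, 0 with an estimated correlation, 0 by fry and 1 with the mean of all kept probe sets per gene, and ranged from 1 to 7 over left-out arrays; the cause was not tested. The ribosomal list turned from 0.35 to −0.12 without PBS replicate 1 (range −0.12 to 0.84), where 12 of 30 list medians changed sign. They numbered 7 without PBS replicate 2, 5 without rhLH replicate 3 and 5 without rhLH replicate 4. Centring arrays on their medians moved the median of all probe sets by 0.11, from −0.04 to 0.08, and kept 4 list calls. Of 76 named genes, 10 changed sign at least once, none of them among the 20 of the first naming rule, whose groups do not overlap by selection, so that most alternatives could not turn them. No paired analysis was possible because the groups share no replicate numbers. On dim probe sets the signal over background limits what can be read.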

Other observations

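The genes of this part were chosen after their values were seen. ISG15 had a signal of 14059 on rhLH replicate 3 against 653 on rhLH replicate 4 and 150.2 and 1447 on the PBS arrays, IFIT1 had 11594 against 855, 651 and 1057, and MX1 had 10389.5 against 575, 311 and 1350.1. Of 12 interferon-stimulated genes picked by hand, for which no list test was run, 10 had their highest signal on rhLH replicate 3, by little for OAS2 (2491 against 2198 on PBS replicate 1) and IFI27 (56665 against 49970.0 on PBS replicate 2). IFIT2 and OAS1 had 1528 and 1319 on that array and were highest on PBS replicate 1 (3414 and 2254). A mitochondrial probe set, MmuMitochon.6.1.S1_s_at, had 72318 on rhLH replicate 3 and 3542 to 4465 on the others.

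For 8 genes with at least 2 kept probe sets, each probe set was at least 1.5-fold higher on both rhLH arrays than on both PBS arrays, and for 5 genes each was lower. The other splits of the arrays gave 3 and 5, and 8 and 5. Besides FST, WNT5A and ABHD6 the higher ones included ANGPTL2, a secreted angiopoietin-like protein (log2 1.81 and 1.55), and BCHE, butyrylcholinesterase (1.26, 1.09 and 0.67). The rest were CISH, a feedback inhibitor of cytokine receptors, CYP11B1 (1.95 and 1.17) and LOC714008 (1.94 to 2.62 over 4 probe sets). The lower ones were BCL10, STK17B, NABP1, a single-stranded DNA-binding protein (−1.62, −1.58 and −1.58), RHOBTB1 (−0.92 and −1.11) and SMPDL3A (−0.90 and −1.31). RLN2, which encodes the luteal hormone relaxin, had signals of 26628 and 28681 with rhLH and 19155 and 18901 with PBS, a log2 difference of 0.54 that was 0.53 against PBS replicate 1 and 0.55 against PBS replicate 2.

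PBS replicate 1 held the farthest values of some genes on which the other 3 arrays lay close together. IGFBP5 had 27.2 there and 1496 to 1660.2 elsewhere, APOE 1297 and 21788 to 28410.5, and MYH10 6.67 and 654 to 872. In the other direction CSH2, a placental lactogen gene, had 9725 there and 545 to 642 elsewhere, and CEACAM1 had 3110 and 91.7 to 172.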
